A study of Homo sapiens with 4 samples.

How the data were processed

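Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map oestrogen receptor binding sites in MCF7, an established human breast cancer cell line that expresses the receptor. Per the labels, formaldehyde-fixed chromatin was sonicated, precipitated with an antibody against the receptor and sequenced on Illumina Genome Analyzers. The 4 libraries combine a transgene with a treatment. The transgene was either GFP, a control protein, or HOTAIR, a long non-coding RNA; after hormone starvation the cells received either ethanol, the vehicle, or E2 (oestradiol, the receptor's ligand). Each of the 4 conditions has 1 library. Per the labels, the source of every sample is also given as a prostate tumour, which does not match the cell line named beside it; the cell line name was used.

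The deposited data are 6 lists of merged peaks, 3 for each pair of libraries. The libraries carry the codes m186 to m189 in the file headers. The labels do not use these codes, so no list was assigned to a transgene or a treatment, and the libraries are named by their codes throughout. Nothing below can be read as a comparison of HOTAIR with GFP or of E2 with vehicle. Differences between libraries can still include effects of the transgene or the treatment, which cannot be named without a key to the codes. Within a pair the lists hold peaks specific to the first library, peaks specific to the second, and peaks shared by both. The submitters' processing notes name BWA 0.6.1, HOMER 4.1 and the genome build hg19, without their roles; the aligner and peak caller settings, duplicate filters and any input control are not given in the sources used here. The columns are those of a HOMER peak merge, per the file headers.

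Each deposited row carries a score, in a column that the file headers call only a statistic; its scale is not given in the sources used here. In the lists of library-specific peaks the authors' scores have 1 decimal and all values under 30 are whole multiples of 1 step per library, within a tolerance of 0.051. The step was 0.785 for m186, 0.700 for m187, 0.807 for m188 and 0.864 for m189. If a step is 1 read scaled to a fixed library size, m187 was 1.12 times as deep as m186 and m189 was 0.933 times as deep as m188. The lowest peak stood at 7 steps in m186 and at 8 steps in each of the other libraries. Scores of shared peaks are multiples of 0.05, as a mean of 2 parent scores would be, so they give no separate value for either library. Total read numbers are not in the lists, and the absolute depth is unknown. The score is each peak's own value as the authors listed it, and it was used to rank, describe or filter peaks. The score also enters ratios of medians. Those of specific to shared peaks set lists of the same pair against each other, and they depend on how the scores of shared peaks were made from libraries with different steps. In the closing observations it enters ratios of medians within a list and differences of log2 ratios between lists, which do not depend on a scale factor of a list.

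From the lists, the share of merged peaks found in both libraries was computed for each pair. Peaks of the pairs were then compared by position, counting an overlap of at least 1 bp, and the total matched that of bedtools 2.31.1. Chance overlap was measured by moving the first pair's peaks by 10 to 50 kb to either side, in 10 moves in all. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the variation between cultures. These intervals treat peaks as independent, although peaks crowd in blocks, so they can be too narrow. Ratios of medians carry 95% percentile intervals from 2000 resamplings of the peaks. With 1 library per condition there is no replicate check, no test between libraries was possible, and no p-values are given. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The functions were tested on simulated peaks with planted steps, overlaps, close pairs, dense bins and gaps, and 8 of 8 checks recovered what had been planted.

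The comparisons of shared peaks, of scores and across pairs were fixed before the data were examined, with some of their alternatives. The alternatives using span edges, dense bins, 300 bp or scores of at least 20 were chosen afterwards. Of the rule for named peaks, only the part on the 5 highest scores of each list was run. The parts on genes of the fixed lists and on genes named beforehand needed an annotation and were not run. The other sites, close peaks and bins named below were outside this rule. The division of the genome into peak-free spans of at least 2.5 Mb (peaks within 0.5 Mb of an edge were set apart, together with sequences outside the numbered chromosomes, X and Y, called contigs here and including the mitochondrial genome), the dense 1 Mb bins (at least 10 m186-specific peaks), the search for specific peaks within 300 bp of each other and the ranking of second-pair sites were chosen after the data had been seen. The spans were first defined as the longest of each chromosome, and this was replaced when it was seen to miss other long spans. Shares of peaks in dense bins are of the peaks on the numbered chromosomes, X and Y. The count of genes near peaks in 11 fixed gene lists, the distance of peaks to transcription start sites and the search for 8 binding motifs had also been set out and were not run, because no hg19 annotation or sequence was used here; for the same reason peaks are given by hg19 position, as the lists give it, and not by gene.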

Results

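The lists hold oestrogen receptor ChIP-seq peaks of 4 MCF7 libraries, which the study's title places in a question about whether the non-coding RNA HOTAIR alters oestrogen receptor signalling. The libraries were compared in pairs, m186 with m187 and m188 with m189, and the codes are not tied to a condition. In all, 45657 merged peaks were listed. Library m186 had 5429 peaks, m187 had 7741, m188 had 25379 and m189 had 27958. Each peak of a single library was a window of 150 bp, and shared peaks, which join a window from each library, were 150 to 300 bp wide. The read depth of the libraries is not in the lists. If a step is 1 read, the steps of the scores put m187 at 1.12 times the depth of m186 and m189 at 0.933 times that of m188. If all 4 libraries were also scaled to the same size, the highest depth of the 4 was 1.23 times the lowest. That is a far smaller spread than that of the peak counts, but the scale of the scores is not stated.

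In the first pair, most peaks were listed for 1 library only. The lists held 2406 shared peaks, 3023 specific to m186 and 5335 specific to m187, so that 22.4% of the merged peaks (95% exact interval 21.6 to 23.2) were found in both libraries. The shared peaks made up 44.3% of the m186 peaks and 31.1% of the m187 peaks. Specific peaks were weak. Their median score was 8.6 in m186 and 9.1 in m187, against 16.6 for the shared peaks, which is 0.518 times (95% interval 0.499 to 0.543) and 0.548 times (0.528 to 0.574) the shared median. Among peaks with a score of at least 20, 974 were shared, 92 were specific to m186 and 193 to m187, and the shared part was 77.4% (74.9 to 79.6). Among peaks with at least the median score of the pair it was 35.5%.

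In the second pair, shared peaks were the majority. The lists held 18444 shared peaks, 6935 specific to m188 and 9514 specific to m189, and 52.9% of the merged peaks (52.3 to 53.4) were found in both. The shared peaks made up 72.7% of the m188 peaks and 66.0% of the m189 peaks. The median score was 8.9 for m188-specific and 9.5 for m189-specific peaks, against 21.85 for shared peaks, or 0.407 times (0.400 to 0.415) and 0.435 times (0.427 to 0.478) the shared median. At a score of at least 20 the shared part was 92.4% (91.9 to 92.9), and at or above the median score of the pair it was 80.9%. In both pairs the second library had more specific peaks than the first, by 1.76 times in m187 and 1.37 times in m189. The excess did not change evenly with the score. For m189 over m188 it was 1.90 times at scores of at least 10, 2.09 at 15 and 1.69 at 20. It was 1.30 at 30 and 1.26 at 50, and at 100 each library had 24 specific peaks. For m187 over m186 it was 2.46, 2.60, 2.10, 1.91 and 1.83 times at scores of at least 10, 15, 20, 30 and 50. At 100 there were 12 specific peaks against 4. A set score is not the same number of steps in both libraries of a pair. The step was larger in m189 than in m188, and smaller in m187 than in m186. These changes of the excess with the score therefore depend on the steps as well, and how much they do was not tested.

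**Figure D1:**
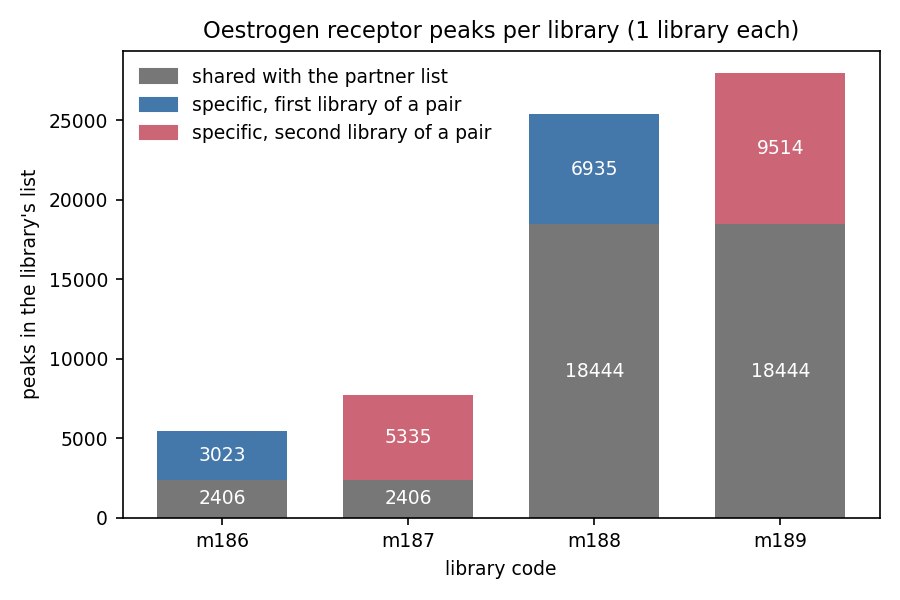
Number of peaks in each library's list (vertical axis, peaks), divided into peaks shared with the partner library (grey) and peaks specific to the first (blue) or second (red) library of the pair; there is 1 library per bar, so no error is shown. The 18444 shared peaks make up most of the m188 and m189 bars, while the 2406 shared peaks are the smaller part of the m186 and m187 bars.

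The same genomic sites recurred across the pairs. Of the 10764 first-pair peaks, 4865 (45.2%, 44.3 to 46.1) overlapped a second-pair peak, against a mean of 1.36% and at most 1.67% when the first-pair peaks were moved. The overlap was 88.4% (87.0 to 89.6) for peaks shared by m186 and m187, 40.0% (38.7 to 41.3) for m187-specific peaks, and 604 of 3023 (18.6% to 21.5%) for m186-specific peaks. Counting only second-pair peaks shared by m188 and m189, 28.3% of the first-pair peaks overlapped. In the other direction, 16.3% (15.8 to 16.8) of the peaks shared by m188 and m189 overlapped a first-pair peak, as did 14.7% (13.8 to 15.5) of the m188-specific and 8.84% (8.28 to 9.43) of the m189-specific peaks. Altogether 1681 of the 2406 peaks shared by the first pair overlapped a peak shared by the second pair, and so were found in all 4 libraries. Of these, 284 (16.9%, 15.1 to 18.8) were on contigs or beside peak-free spans. The part was 17.1% of all peaks shared by m186 and m187 and 3.47% of those shared by m188 and m189.

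The strongest second-pair sites were found far more often in m187 than in m186. Of the 100 highest-scoring sites shared by m188 and m189, leaving out those on contigs and beside peak-free spans, 75 (65.3% to 83.1%) were overlapped by a peak of m187 and 28 (19.5% to 37.9%) by a peak of m186. All 28 of the m186 sites were also in m187, and 47 were in m187 alone. Of the next 900 sites, 32.4% (29.4 to 35.6) were in m187 and 7.22% (5.62 to 9.11) in m186, with 230 in m187 alone and 3 in m186 alone. Among the sites ranked 1001 to 5000 the shares were 11.9% (10.9 to 12.9) and 7.35% (6.56 to 8.20). Among the remaining 12804 they were 12.8% (12.2 to 13.4) and 9.50% (8.99 to 10.0). When the m187 list was shortened to the length of the m186 list by dropping its weakest specific peaks, it still held 72 of the 100 sites. Shared peaks were kept in this cut, so it could lose only sites held by weak m187-specific peaks. It does not show whether the libraries differed in how readily they list a site. There is 1 library behind each value, so these intervals do not cover the difference between cultures.

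**Figure D2:**
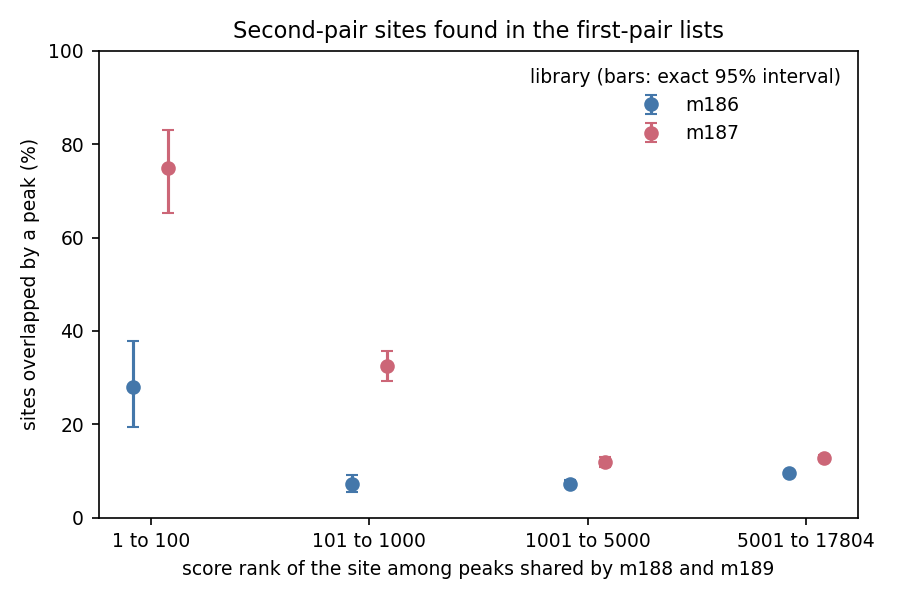
Percent of the sites shared by m188 and m189 (vertical axis) that a peak of m186 (blue) or m187 (red) overlaps, by the score rank of the site (horizontal axis, rank 1 is the highest score); points are single libraries and bars exact 95% binomial intervals. The libraries lie farthest apart among the first 100 sites, at 28 against 75, and both lie between 7.35% and 12.8% beyond rank 1000.

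The sites named here are the top of the same ranking, and so are not further support for it. Of the 10 highest-scoring second-pair sites of this ranking, all had a first-pair peak within 300 bp; 6 of these were specific to m187 and 4 shared by m186 and m187. On chromosome 20, the site at 52811967 to 52812124 scored 8013 in the second pair, and the m187-specific peak there, at 52811958 to 52812108, scored 56.7. The sites at 52740317 to 52740489 and at 52765739 to 52765890 of the same chromosome scored 5418 and 5305, and their m187-specific peaks 75.6 and 61.6. A further site there, at 49343985 to 49344151, scored 2401, with an m187-specific peak at 153. On chromosome 17, the site at 59800727 to 59800884 scored 4195, with an m187-specific peak scoring 235, one of the 5 highest m187-specific scores. The site at 49021848 to 49022011 scored 3828, with an m187-specific peak at 22.4. Sites with a shared first-pair peak were on chromosome 21 at 43796531 to 43796689 (score 3894; first pair 116), on chromosome 2 at 11638785 to 11638936 (3828; 105), on chromosome 17 at 56717120 to 56717276 (3096; 169) and on chromosome 8 at 98776581 to 98776757 (2438; 77.2). The scores of the pairs are set side by side as listed, since their scale is not stated. Most of these sites were on chromosomes 17 and 20, where MCF7 is known to carry amplified segments. Whether extra DNA copies raised their scores was not tested.

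The highest scores shared by the first pair lay in other places. Of the 50 highest peaks shared by m186 and m187, 39 were on contigs or within 0.5 Mb of 1 of the 71 spans of at least 2.5 Mb without a peak in any list, against 4 of the 50 highest peaks shared by m188 and m189. Among library-specific peaks the number was 21 of 50 in m186, 17 in m187, 16 in m188 and 9 in m189, so that the pairs lay closer together there. Over all shared peaks, 412 of 2406 (17.1%, 15.6 to 18.7) were at such places in the first pair and 640 of 18444 (3.47%, 3.21 to 3.74) in the second, so that the second pair had more of them and a lower share. The highest first-pair score, 5657, was on chromosome 1 at 121485120 to 121485274, at the edge of a span of 21.1 Mb; the second pair had a shared peak there with a score of 5254. The following scores were 1634 on chromosome 19 at 27732009 to 27732206, 944 and 843 on chromosome 10 at 42596981 to 42597134 and at 42385130 to 42385292, and 833 on chromosome 7 at 61968968 to 61969123, the last of which was not within 0.5 Mb of such a span. In the second pair, a shared peak on the unplaced contig gl000220 at 134269 to 134426 scored 6306. The highest m187-specific score, 1076, was on the mitochondrial genome at 32 to 182. The m186-specific list was led by peaks on chromosome 21 at 9826136 to 9826286 (273), chromosome 5 at 10779 to 10929 (163), chromosome 8 at 43092834 to 43092984 (142), chromosome 1 at 569367 to 569517 (124.9) and chromosome 10 at 42356410 to 42356560 (93.4). Of these, the peaks on chromosomes 5, 8 and 1 were not within 0.5 Mb of a span. The m186-specific peaks on chromosomes 21 and 5 lay within 300 bp of m187-specific peaks scoring 318.6 and 180.7. Besides the mitochondrial peak and that on chromosome 17, the m187-specific list was led by peaks on chromosome 10 at 42385494 to 42385644 (540.6), chromosome 7 at 61970288 to 61970438 (414.5) and chromosome 21 at 9825873 to 9826023 (319), and the chromosome 7 peak was again outside that distance.

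Library-specific peaks had a larger share than shared peaks on chromosomes 1, 3, 9, 17 and 20 as a group. These 5 chromosomes, named after their counts were seen, held 48.0% (46.2 to 49.8) of the m186-specific, 41.3% (40.0 to 42.6) of the m187-specific, 35.2% (34.0 to 36.3) of the m188-specific and 32.6% (31.6 to 33.5) of the m189-specific peaks. Of the shared peaks they held 30.2% (28.4 to 32.1) in the first pair and 28.6% (28.0 to 29.3) in the second, an order that turned at or above the median score of each list, where they held 26.8% and 28.9%. Not each of the 5 stood out by itself. On chromosome 3 the m188-specific share, 5.84% (5.30 to 6.42), was not above the 5.92% of the peaks shared by m188 and m189, and on chromosome 17 the m189-specific share, 4.80% (4.38 to 5.25), was not above their 4.56% beyond its interval. The crowding was in blocks. The 69 bins of 1 Mb with at least 10 m186-specific peaks were 2.58% of the 2677 bins with any peak, and held 38.5% of the m186-specific peaks, by which they were chosen. The same bins held 24.4% (23.2 to 25.6) of the m187-specific, 17.9% (1224 of 6855) of the m188-specific and 11.8% (1116 of 9434) of the m189-specific peaks, and 7.41% (7.04 to 7.80) of the peaks shared by m188 and m189. They held 12.7% (11.4 to 14.2) of the peaks shared by m186 and m187, so the crowding was not limited to library-specific peaks. The longest block, on chromosome 9 from 107 to 116 Mb, held 229 m186-specific, 233 m187-specific, 191 m188-specific and 184 m189-specific peaks. On chromosome 20, the block from 55 to 63 Mb held 128, 149, 176 and 129 of them. Further blocks of 4 Mb or more lay on chromosome 1 from 106 to 110 Mb and from 114 to 119 Mb, on chromosome 3 from 61 to 65 Mb and on chromosome 17 from 60 to 64 Mb.

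**Figure D3:**
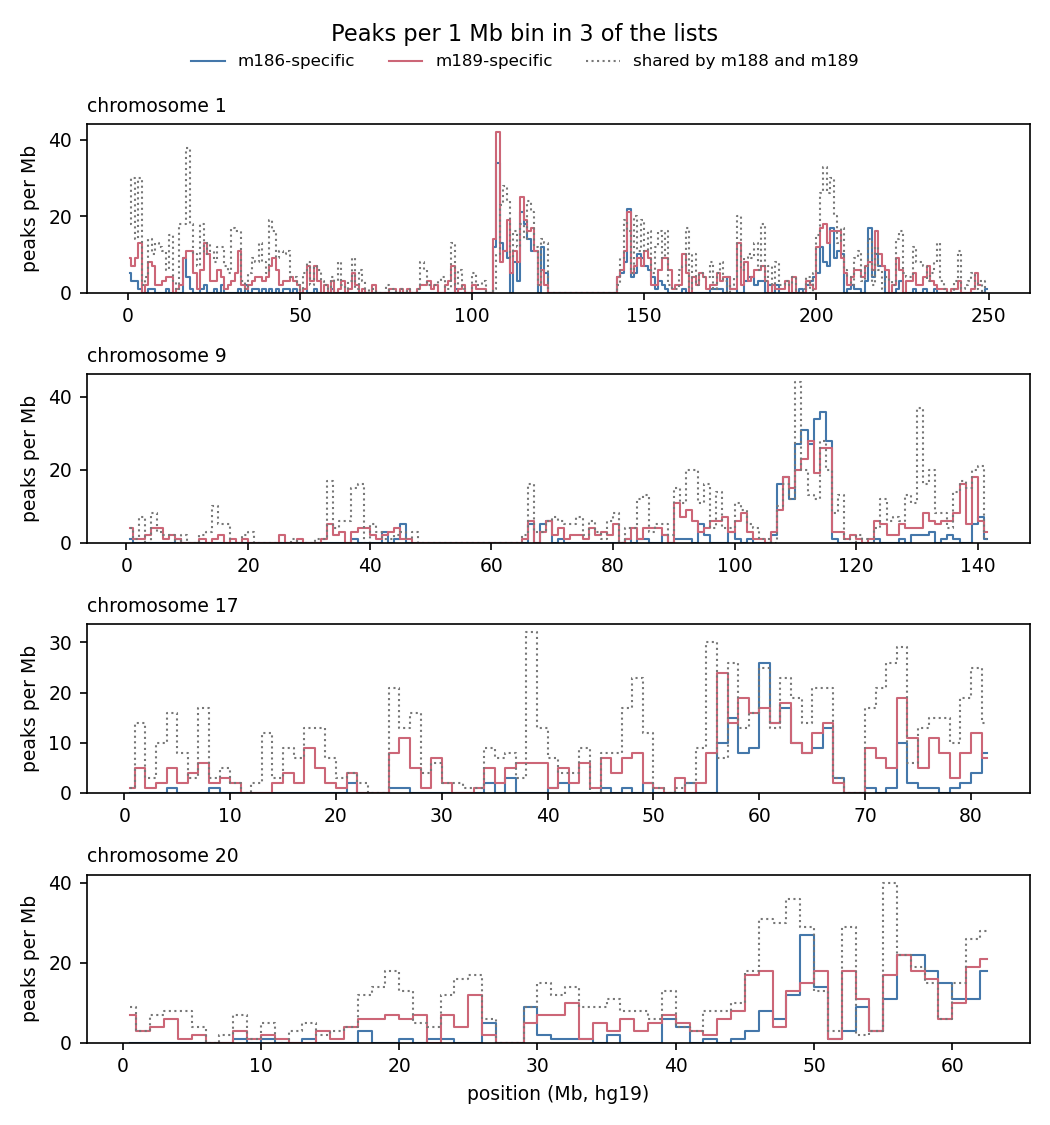
Peaks per bin of 1 Mb (vertical axes) along chromosomes 1, 9, 17 and 20 (horizontal axes, Mb in hg19) for m186-specific peaks (blue), m189-specific peaks (red) and peaks shared by m188 and m189 (grey, dotted). The m186-specific and m189-specific peaks rise together in the same blocks, such as 107 to 116 Mb of chromosome 9, which holds 229 and 184 of them.

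A small part of the peaks listed as specific to each library of a pair, some of the strongest among them, lay next to each other. In the second pair, 442 m188-specific peaks had an m189-specific peak within 300 bp, against a mean of 39.9 and at most 48 when 1 list was moved by 5 to 50 kb. In the first pair the number was 185, against a mean of 25.7 and at most 38. These were 6.37% of the m188-specific and 4.65% of the m189-specific peaks, and 6.12% of the m186-specific and 3.47% of the m187-specific peaks. Most had low scores, and both scores were at least 20 in 54 of the 442 and 15 of the 185 cases. In the whole lists, 306 of 6935 m188-specific and 517 of 9514 m189-specific peaks scored at least 20. In the first pair, 92 of 3023 m186-specific and 193 of 5335 m187-specific peaks did, so close peaks were more often strong in both pairs. Their median scores were 11.3 (m188), 11.2 (m189), 8.6 (m186) and 10.5 (m187), against 8.9, 9.5, 8.6 and 9.1 in the whole lists. The 3 strongest second-pair cases included the highest peaks of both specific lists. On chromosome 8, the m188-specific peak at 128871873 to 128872023 scored 1462 and the m189-specific peak at 128872083 to 128872233 scored 2039.9. On chromosome 16, the peaks at 1241648 to 1241798 and at 1241447 to 1241597 scored 1094 and 1102. On chromosome 19, those at 41427112 to 41427262 and at 41427336 to 41427486 scored 939 and 840.2. The other leading m188-specific peaks were on chromosome 20 at 47314405 to 47314555 (1002) and on contig gl000220 at 118643 to 118793 (904). The other leading m189-specific peaks were on chromosome 7 at 61968909 to 61969059 (774) and on chromosome 10 at 42392655 to 42392805 (694). That on chromosome 7 overlaps the peak shared by m186 and m187 at 61968968 to 61969123, so it is specific only within its pair. Counting peaks within 300 bp as shared made the shared part 24.5% in the first pair and 54.8% in the second.

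**Figure D4:**
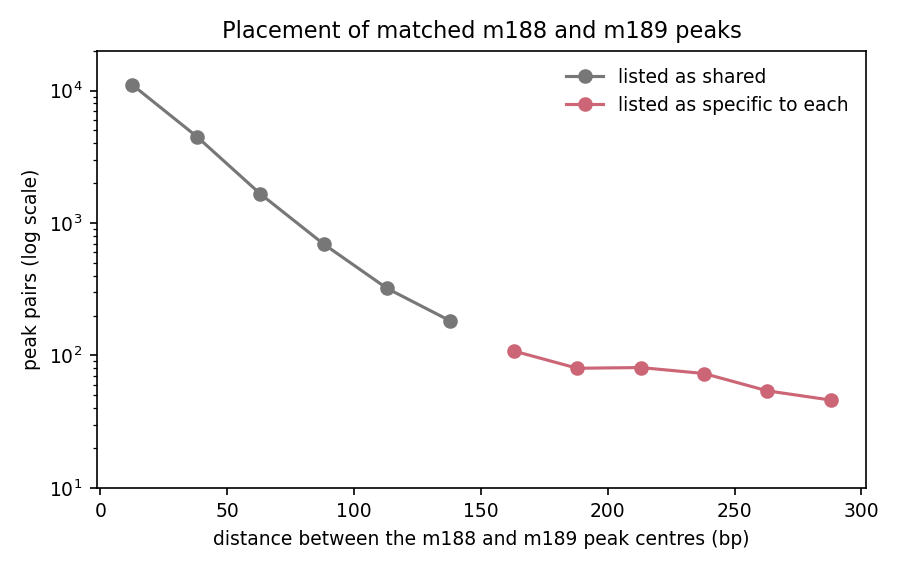
Number of pairs of m188 and m189 peaks (vertical axis, log scale) by the distance between their centres (horizontal axis, bp, in steps of 25 bp); grey points are pairs merged as shared and red points pairs in which each peak is listed as specific to its library. The listing changes at 150 bp, where the counts pass from 182 to 108.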

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

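Of 41 alternatives computed for 15 results, 14 stayed within the 95% interval of the reported value and 27 did not; the shared part of the first pair stayed below that of the second under each alternative run for both. Score filters moved the shared part most. At or above the median score of the pair it was 35.45% for m186 with m187 and 80.92% for m188 with m189, and at scores of at least 20 it was 77.36% and 92.38%. Counting specific peaks within 1000 bp as shared gave 26.7% and 56.41%, and within 300 bp 24.49% and 54.82%. Without the dense bins the values were 26.24% and 54.78%. Leaving out X, Y, the mitochondrial genome and contigs gave 21.47% and 52.74%, and leaving out span edges and contigs gave 20.12% and 52.79%; of these, both values of the second pair stayed within its interval. No specific peaks of a pair overlap, so counting a 1 bp overlap as shared changed nothing. The 45.2% of first-pair peaks found in the second pair became 38.98% when 0.5 of the shorter peak had to overlap, 58.7% with centres within 1000 bp, 60.71% at or above the median score, 28.27% against shared second-pair peaks only, 43.77% without span edges and contigs and 50.95% without dense bins. The ratio of specific to shared scores, from means of log2 scores, was 0.4388 for m186, 0.471 for m187, 0.3515 for m188 and 0.3792 for m189. At or above the median score of each list, the share on chromosomes 1, 3, 9, 17 and 20 was 57.07% for m186-specific, 44.66% for m187-specific, 37.87% for m188-specific and 34.04% for m189-specific peaks, and 26.83% for peaks shared by m186 and m187, which put the last below the 28.93% of peaks shared by m188 and m189 and so turned the order of the shared lists; the cause was not tested. The 28 and 75 of 100 strongest sites found in m186 and m187 were 24 and 69 outside dense bins, and 29 and 75 with centres within 300 bp. The alternatives on span edges, dense bins, 300 bp, scores of at least 20 and the 100 sites were chosen after seeing the data. The alternatives set out for gene lists, motifs and transcription start sites were not run, for lack of an hg19 annotation and sequence. Weak peaks stand at 7 or 8 steps of the score, so at this depth a site listed for 1 library is not shown to be absent from its partner.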

Other observations

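The tests of shared scores in dense bins, of the density of shared peaks in them and of the offset counts were set out before their results were seen; the other tests here were chosen afterwards. The library codes are tied to no condition, so no biological explanation from the groups of the design was tested.

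The peaks shared by m188 and m189 were most crowded in 5 bins of 1 Mb that lie on chromosomes 9, 16, 20 and 21. The bin from 43 to 44 Mb of chromosome 21 held 46 of them, among them the site at 43796531 named for its score. The bin from 85 to 86 Mb of chromosome 16 held 45, that from 110 to 111 Mb of chromosome 9 held 44, that from 46 to 47 Mb of chromosome 21 held 42 and that from 55 to 56 Mb of chromosome 20 held 40. Of all first-pair peaks, 21.1% (1127 of 5335) of the m187-specific and 7.77% (235 of 3023) of the m186-specific peaks lay in a peak shared by m188 and m189, against 69.9% of those shared by m186 and m187. Of those with a score of at least 10, 36.4% (34.0 to 38.7) of the m187-specific and 14.9% (12.3 to 17.8) of the m186-specific peaks did so, against 78.8% (76.9 to 80.6) of the shared ones.

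Peaks were dense in a few blocks, library-specific peaks most of all in m186, whose peaks chose the bins. Noise of a single library is argued against: the same bins held m189-specific peaks at 4.59 times (95% interval 4.34 to 4.85) their share of bins. That interval treats the peaks as independent, although they lie in blocks, and may be too narrow. A candidate explanation is extra DNA copies, since MCF7 is known to carry amplified segments on the long arms of chromosomes 17 and 20, but no copy number data were used here. The scores did not decide it. For peaks shared by m188 and m189 they were 1.056 times as high inside the bins as outside, below the bound set beforehand against extra copies. The interval (0.971 to 1.13), weighed only after this value was seen, reaches above that bound. For peaks shared by m186 and m187 the scores were 0.844 times as high (0.768 to 0.936). For the library-specific lists they were 1.08 to 1.09 times as high. There the medians were a single step of the score apart, such as 9.7 against 8.9 for m188-specific peaks. A median over lists with a threshold could also fall where more copies bring weak peaks over it. Real clusters of receptor sites stay open, as peaks shared by m188 and m189 were 0.6267 times as dense in the bins as m189-specific peaks, between the bounds set for and against; in the first pair, shared peaks were at 4.94 times (4.42 to 5.50) their share of bins and m187-specific peaks at 9.45 times (9.01 to 9.91), so that shared peaks were the less dense in both pairs.

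The highest scores of the peaks shared by m186 and m187 lay beside peak-free spans and on contigs; of the 131 first-pair shared peaks with a score of at least 100, 86 were at these places. Reads of repeats that are collapsed on the assembly could give such peaks in every library, and receptor binding as at other sites could too. The log2 ratio of second-pair to first-pair score was compared between these places and elsewhere, as a difference that does not depend on the scale of the scores. Over all matched shared peaks it was -0.30 (interval -0.34 to -0.25), and the test was then narrowed to first-pair scores of at least 100, where it was -0.2856 (-0.48 to -0.13; 78 against 41 peaks). The bounds were set for scores of at least 100 only, and the value there lies between them, so the explanations cannot be told apart here. Only peaks shared within both pairs were matched. Sites listed in the first pair for m187 alone, among them some of the strongest second-pair sites, were therefore left out of the comparison. The spans were defined by the absence of peaks and not by known repeats, so each group may mix repeats with other sites.

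A small part of the library-specific peaks, 3.47% to 6.37% of each list, lay within 300 bp of a peak specific to the partner library. Chance proximity is argued against, as there were 11.07 times as many such second-pair cases as after moving a list, and 7.21 times as many first-pair cases. One site split by the placement of its windows may account for them: in the second pair the number of offsets just above the 150 bp limit of a merge was 0.5934 times that just below it, in the range set for this explanation, and in the first pair the numbers were 36 and 68. Across these peaks, which are not independent replicates, the scores of the close peaks had a Spearman correlation of 0.617 in the second pair and 0.438 in the first. Separate neighbouring sites were not tested and stay open, since the ratio of offsets could fall in that range for them too. Within m188 and within m189 no peaks lay within 300 bp of each other, and the smallest distances were 311 and 336 bp. The list of a single library therefore does not show whether such close neighbours exist.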
